A study of Homo sapiens with 4 samples.

How the data were processed

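Total RNA was sequenced from 4 samples of imatinib-resistant K562 cells, 2 labelled VC and 2 labelled KD. Per the labels' protocols, RNA was extracted with a combined DNA, RNA and miRNA column kit and libraries were made with an NEB Ultra RNA-Seq kit from total RNA. The labels give no rRNA removal step, no read length, no strand setting and no sequencing batch. Groups and replicate numbers were taken from the sample titles. The titles number the KD samples 1 and 2 while the names of their deposited files carry 2 and 3, so a shared replicate number need not mark a shared origin. Nothing in the labels says that the 2 samples of a group came from separate cultures. The p-values and intervals therefore measure only the spread between these samples, which may be technical.

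The authors quantified each library by itself, and the deposited tables have the columns that Salmon writes. Per the submitters' processing notes the tool was Salmon 0.8.1 and the genome build hg19. Per the file headers, each transcript has a length, an effective length, a TPM value and a number of reads. The deposited read numbers are estimated counts that need not be whole, because Salmon divides a read that matches several transcripts among them. The deposited TPM values are those counts divided by effective length and scaled to the same total per library by the authors' Salmon run. No resampling estimates of the assignment error were used here. The Salmon index and options are not given in the sources used here.

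The features are 78631 transcripts with identifiers in the style of UCSC known genes, in the same order and with the same lengths in all 4 tables. The files do not pair these identifiers with gene names, and the reference tables at hand (RefSeq gene records of assembly GRCh38.p14 and GENCODE names) list gene names under other identifiers. Exact matching against the synonyms in the RefSeq table named 3 identifiers of the 78631. None of the 3 passed the expression filter. The analysis therefore ran on the transcript identifiers as deposited, which is what the design fixed before the data were examined prescribed for this case. The planned check of PLAG1 itself and the 44 gene lists fixed beforehand need gene names and were not analysed here. The same holds for the planned setting without mitochondrial, ribosomal and globin genes. No coordinates are reported, since none are in the files.

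Estimated counts were rounded to whole numbers. Transcripts were kept with the default expression filter of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total count 15), which left 35776 transcripts holding 99.6% of the rounded reads. TMM factors were computed, and KD was compared with VC by edgeR's quasi-likelihood F-test with robust estimation, group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are KD relative to VC. Levels per library are given as CPM, the reads scaled to a common library size. Log2 CPM values used a prior count of 2. Intervals of fold changes are 95% intervals from limma-voom (limma 3.58.1) on the same transcripts, a description added after the data were seen. Shares of reads were compared by an exact two-sided permutation test, which with 2 against 2 libraries cannot give a p below 0.333.

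The totals per library ran from 16450627 to 20613436 rounded reads. A transcript with 0 reads in a library has an upper limit of 3 reads there, which is 0.146 to 0.182 CPM. These limits cover counting error only, not the error of dividing reads among overlapping transcripts.

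The naming rule, fixed before the data were examined, took the 10 transcripts with the smallest p where fewer than 5 passed the threshold. Of these, the first 2 higher and the first 2 lower are given, because identifiers without gene names say little. The most abundant transcripts are also named, chosen after their values were seen.

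The test was tried on simulated data. Counts for the 35776 tested transcripts were drawn from the real means and library sizes. Of these, 200 with a mean of at least 5 CPM were changed by folds of 2, 4, 8 or 16. The shares called therefore do not cover transcripts below that level. With a low simulated dispersion of 0.01, 100% of the changed transcripts were called at each fold, and the median fitted log2 change at 4-fold was 2.01. With the dispersions estimated from these libraries, 2.04% of the 2-fold, 20% of the 4-fold, 54% of the 8-fold and 84% of the 16-fold changes were called in this comparison. There the unchanged transcripts had a median absolute log2 change of 0.461. In the data it was 0.699 under 1 CPM, 0.526 at 1 to under 5 CPM, 0.231 at 5 to under 50 CPM, and less above that. The simulated spread was not matched to the data by level. It may exceed the real one, so the shares called may be too low.

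Alternatives planned before the data were examined were RLE size factors, library size alone, upper-quartile factors, no low-count filter, a filter of at least 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), counts corrected for effective length, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were a crossed block, leaving out the 10 most abundant transcripts, only transcripts with whole-number estimates in all 4 libraries (tolerance 1e-09), sums over 5 consecutive rows of the tables, and only transcripts with a mean of at least 5 CPM.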

Results

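Imatinib-resistant K562 cells were compared under 2 conditions, labelled KD and VC, by RNA sequencing of total RNA. K562 is a human chronic myeloid leukaemia line that carries the BCR-ABL1 fusion, the kinase that imatinib inhibits. PLAG1, the gene named in the labels, encodes a zinc finger transcription factor. KD is the usual abbreviation of knockdown, and VC, which the labels do not spell out, is the group KD is set against here. Each group had 2 libraries. The totals were 17833366 reads for VC 1, 20613436 for VC 2, 16450627 for KD 1 and 19997430 for KD 2, after rounding of the estimated reads. Reads were found for 56255 of the 78631 listed transcripts in at least 1 library, and each library held between 42488 and 44225 detected transcripts. The tables list transcripts by identifiers that they do not pair with gene names. The level of PLAG1, which would check the labels, was therefore not analysed here, and all values below are per transcript and not per gene. KD and VC stand below for the libraries so labelled.

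The first question was which RNAs made up the libraries, and whether that make-up differed between the groups. Short transcripts dominated on the TPM scale but not by reads. Transcripts of 200 to under 500 nt took 10.9% ± 0.828 of the reads in VC and 10.1% ± 1.79 in KD (SD, n = 2 each; exact permutation p = 0.667). On the TPM scale, which divides by length, the same class took 65.7% ± 2.37 in VC and 63.7% ± 1.97 in KD (SD, n = 2 each). Most of that came from the transcripts uc021rsp.1 and uc021rst.1, both 301 nt long. uc021rsp.1 held 23.3% ± 0.916 of TPM in VC and 23.3% ± 0.767 in KD, and uc021rst.1 held 23.0% ± 0.984 in VC and 23.3% ± 0.608 in KD (SD, n = 2 each). No sequences were compared, so whether the 2 share reads is not known. Their log2 fold changes from VC to KD were -0.09 (SE 0.197) and -0.08 (SE 0.172), with an edgeR adjusted p of 1.00 for both.

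The most read long transcript was uc022brd.2, 13513 nt, with 3.38% ± 0.422 of the reads in VC and 3.70% ± 1.88 in KD (SD, n = 2 each). Its share was 5.03% in KD 1 and 2.37% in KD 2, so the KD libraries lay on both sides of VC 1 at 3.68% and VC 2 at 3.08%. Among the 10 most read transcripts, the largest log2 fold change was that of uc003zxh.2, 268 nt, which took 0.562% ± 0.0167 of the reads in VC and 0.378% ± 0.0917 in KD (SD, n = 2 each). Its log2 fold change was -0.59 (SE 0.221), with an edgeR adjusted p of 1.00, so it did not pass the test. The 10 most read transcripts together held between 14.15% and 15.96% of the reads of each library. Of the other length classes, 1000 to under 2000 nt took 18.4% ± 0.00583 of the reads in VC and 19.2% ± 0.504 in KD (SD, n = 2 each; exact permutation p = 0.333, the smallest that 2 against 2 can give). Transcripts of 8000 nt or more took 9.81% ± 0.257 in VC and 9.81% ± 1.83 in KD (SD, n = 2 each; exact permutation p = 1). The 7 length classes were tested in 1 family, and none can pass a threshold of 0.05 in this design.

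The second question was how far the libraries of a group resembled each other against those of the other group. Over the 35776 tested transcripts, the median absolute difference in log2 CPM was 0.54 between the VC libraries and 0.47 between the KD libraries. Between groups it was 0.53 for VC 1 and KD 1, 0.50 for VC 1 and KD 2, 0.47 for VC 2 and KD 1, and 0.44 for VC 2 and KD 2. The closest pair, VC 2 and KD 2, and the pair farthest apart, VC 1 and VC 2, thus went against the group labels. Every pair with VC 1 lay farther apart than every pair without it. The distances thus set VC 1 apart from the other libraries. The median gap between length and effective length of long transcripts was 226 nt in VC 1 and 246 nt in KD 2. It was 250 nt in VC 2 and 265 nt in KD 1. Whether this difference between libraries bears on the distances was not tested. The mean distance between groups was 0.957 times the mean distance within groups. The same order at both ends was found among the 3858 transcripts with a mean of at least 50 CPM, where the VC libraries differed by 0.26, the KD libraries by 0.18, and VC 2 and KD 2 by 0.16. Across all tested transcripts, Pearson's r of log2 CPM lay between 0.790 and 0.824 for the 6 pairs, a correlation across transcripts, which are not independent replicates. No 2 libraries were near enough to be 1 library deposited more than once.

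**Figure D1:**
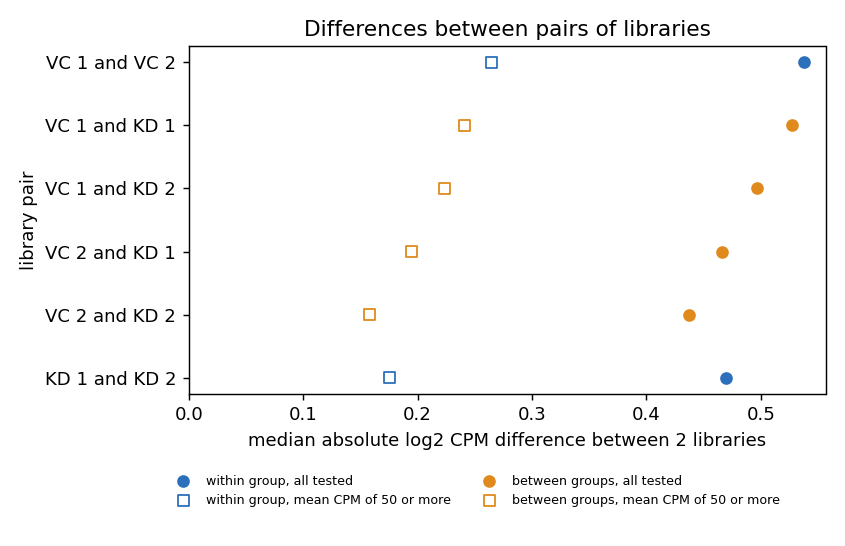
Median absolute difference in log2 CPM (x axis) for each of the 6 pairs of libraries (y axis), for all 35776 tested transcripts (filled circles) and for the 3858 with a mean of at least 50 CPM (open squares). Pairs within a group are blue and pairs between groups orange; VC 1 and VC 2 differ most (0.54 and 0.26), and VC 2 and KD 2 least (0.44 and 0.16).

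The third question, which the series title names, was which transcripts differ between KD and VC. No transcript rose or fell past the threshold. With edgeR's quasi-likelihood test 0 of 35776 transcripts had an adjusted p below 0.05, and the smallest adjusted p was 0.981. At an unadjusted p below 0.05 there were 1399 transcripts, 624 higher and 775 lower in KD, which is 3.91% of those tested where chance gives 5%. Without either VC library more of the transcripts at that level were higher in KD, and without either KD library more were lower. The side thus followed the group cut to 1 library. These fits therefore cannot show whether the balance rests on a single library. limma-voom also called 0, with 948 at an unadjusted p below 0.05 (410 higher, 538 lower in KD), and limma on log2(TPM + 1) called 0, with 1754 (898 higher, 856 lower). DESeq2 called 345 transcripts, 147 higher and 198 lower in KD. Of those 345, 297 had 0 reads in both libraries of 1 group, against 796 such transcripts among all 35776 tested.

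The transcripts with the smallest p were of that kind. All 10 with the smallest edgeR p had 0 reads in both libraries of 1 group, 7 of them in VC and 3 in KD. The first was uc002fxp.3, 7953 nt, with 0 reads in both VC libraries and 389 and 548 in KD, or 25.5 CPM ± 2.66 (SD, n = 2). Against the limit of 3 reads per library that a count of 0 allows, this is at least 163-fold higher in KD. uc022cel.1, 4270 nt, had 0 reads in both VC libraries and 231 and 386 in KD, which is at least 106-fold higher. In the other direction, uc003ajg.3, 7104 nt, had 254 and 409 reads in VC and 0 in both KD libraries, at least 103-fold lower in KD. uc010pne.2, 11585 nt, had 210 and 289 reads in VC and 0 in both KD libraries, at least 77.6-fold lower. None of these 4 passed the edgeR test (adjusted p = 0.981 for each), and DESeq2 gave them adjusted p-values from 1.84e-09 to 3.23e-07. The bounds take the mean of the other group as observed. They allow for counting error at 0 reads only, not for the error or spread of that mean. A transcript at 0 reads can also share its sequence with another transcript that received those reads.

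**Figure D2:**
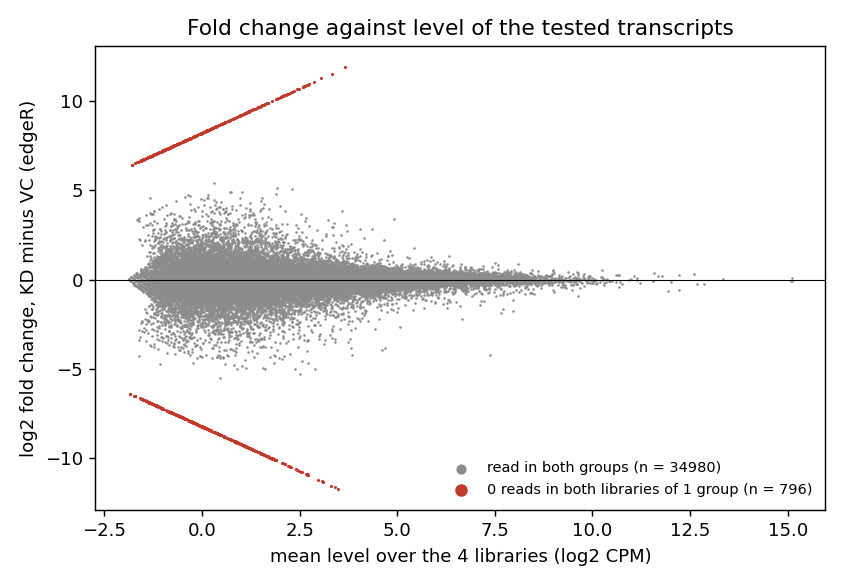
Log2 fold change of KD relative to VC from edgeR (y axis) against mean log2 CPM over the 4 libraries (x axis), 1 point per tested transcript. The 796 transcripts with 0 reads in both libraries of 1 group (red) form the 2 outer lines, where the fitted fold depends on the prior count; the other 34980 (grey) narrow around 0 as the level rises.

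Among well-read transcripts most fitted changes were small. Of the 16936 transcripts with a mean of at least 5 CPM, 95.3% had a fitted change under 2-fold, and the median log2 fold change was -0.01. The remaining 797 were 288 higher and 509 lower by at least 2-fold, none past the test. The 2 KD libraries lay on one side of both VC libraries for 29.9% of the 16936, where chance gives 33.3%. How much can be said of each varied with its level. The intervals used rest on the spread of these samples and include no separate estimate of read assignment error. They therefore bear on these samples and not on the condition in general. The limma-voom 95% interval of the log2 fold change excluded a change of 2-fold in either direction for 8862 of the 16936 (52.3%), with a median half-width of 0.75. At a mean of at least 50 CPM it did so for 3386 of 3858 (87.8%), with a median half-width of 0.49. For transcripts of 1 to under 5 CPM the share was 0.284%, so a change of 2-fold could rarely be excluded at that level.

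The share of transcripts at an unadjusted p below 0.05 varied with transcript length, and from 500 nt upward it rose at each step. It was 0 of 38 transcripts under 200 nt, 3.13% (10 of 319) for 200 to under 500 nt, 1.83% for 500 to under 1000 nt, 2.49% for 1000 to under 2000 nt, 4.08% for 2000 to under 4000 nt, 5.33% for 4000 to under 8000 nt and 7.27% for 8000 nt or more. By level it was 7.02% under 1 CPM and between 2.82% and 3.84% in each class above that. Of the 1399, 791 had 0 reads in both libraries of 1 group.

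The RefSeq synonyms gave a gene name for 3 identifiers, all antisense RNAs and all too weakly read to be tested. ZNF350-AS1 (uc002pyc.3) had 0 and 8 reads in VC and 5 and 4 in KD. ACTA2-AS1 (uc001kfo.1) had 0 and 3.21 estimated reads in VC and 0 and 2.05 in KD. HNF4A-AS1 (uc002xlx.3) had 0 reads in all 4 libraries.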

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

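The count of 0 transcripts past the threshold was the same under 18 of 19 alternatives, 5 of them chosen after seeing the data. DESeq2 was the exception, with 345 calls, 329 of them with a fold of at least 2, and 3468 adjusted p-values left undefined by its filtering. The number at an unadjusted p below 0.05 (1399) fell to 730 with the replicate number as a block and to 797 with the crossed block, both of which leave 1 residual degree of freedom, and neither block gave a call. It was 76 with whole-number reads only, 442 for sums over 5 consecutive rows and 490 at a mean of at least 5 CPM, where fewer units were tested (3111, 13117 and 16936). Leaving out 1 library gave 1500 to 2614, with the highest value without VC replicate 2. There the lone library is assumed to vary like the other group. The numbers 1 and 2 in the titles do not pair the samples by any label, and the KD files carry other numbers. The correlation of the deviations of same-numbered libraries was -0.01 over all tested transcripts and -0.13 at a mean of at least 50 CPM. The sign of the latter means that deviations went weakly with the crossed numbers, VC 1 with KD 2 and VC 2 with KD 1. The 4 named transcripts have 0 reads in 1 group, so no setting could turn their direction. On log2(TPM + 1) their log2 fold changes shrank to 1.66 for uc002fxp.3, 1.88 for uc022cel.1, -1.36 for uc003ajg.3 and -0.78 for uc010pne.2. Planned settings for PLAG1 and the gene lists, and the one without mitochondrial, ribosomal and globin genes, were not run because they need gene names; transcript identifiers as units were already the level of the test. The spread of 2 libraries limits what can be called. In data simulated at this depth, 4-fold changes were placed only in transcripts with a mean of at least 5 CPM. Of these changes, 20% were called with the estimated dispersions and 100% with a low one. The 20% may be too low, since the simulated spread may exceed the real one. At 1 to under 5 CPM the 95% interval excluded a 2-fold change for 0.284% of transcripts; depth and spread were not separated there.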

Other observations

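The splits of the libraries, the comparison of DESeq2 calls with neighbouring rows and the test for a wrong label were chosen only after the results they bear on were seen. The simulation and the neighbour test of transcripts read in 1 group only were set out before their results.

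Many transcripts were read in both libraries of 1 group and in neither of the other. With at least 10 reads in each of 2 libraries, 362 were read only in KD and 447 only in VC, 809 in all. The 2 other ways to split the 4 libraries into pairs gave 914 and 876, so differences between single libraries give as many. For the 809, the 5 rows on each side in the tables offset a median of 64.2% of the change, against -4.32% to 3.56% (central 95%) for rows placed at random. This is consistent with read assignment between overlapping transcripts, if neighbouring rows hold overlapping transcripts, which the files do not state. A real change of isoform under knockdown would give the same offset and stays open, but the count for KD against VC did not exceed those of the other splits.

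DESeq2 called 345 transcripts between KD and VC, and 369 and 1370 in the other splits, the 1370 for VC 1 and KD 2 against VC 2 and KD 1. Differences between single libraries are thus enough to give as many calls, and the 1370 of the other split would point to a structure of the samples. Transcripts of 200 to under 500 nt took 11.4% of the reads in VC 1 and 11.4% in KD 2. They took 10.3% in VC 2 and 8.82% in KD 1, so their share divided the libraries as that split does. This class was picked after the calls were seen, and chance gives 33.3% for any 1 class. The shares of 500 to under 1000 nt and 2000 to under 4000 nt divided them likewise, and those of the remaining classes did not. The gap between length and effective length given above also divided them so. A link of any of these to the calls was not tested. edgeR and limma-voom called 0 in both other splits. At an unadjusted p below 0.05 limma-voom had 948 transcripts for KD against VC, and 1344 and 1493 in the other splits, the 1493 in the split with 1370. edgeR had 1399, 1822 and 1807 in the same order. For the 297 calls with 0 reads in 1 group, neighbouring rows offset a median of 61.9% of the change (random rows -4.82% to 4.44%), so read assignment may account for much of this part. For the 48 calls read in both groups the value was -5.04% (random rows -2.81% to 2.69%). It lay below the random range, and neighbouring rows moved the other way for 43.75% of the 48 (random rows 35.42% to 62.5%). Neither measure showed an offset by rows within the window. The outcome set as counting against read assignment was a value within the random range, so the first measure gave no verdict. Overlapping transcripts may also lie outside the window, so read assignment and an effect of the knockdown cannot be told apart. The other splits gave 60 and 669 calls read on both sides.

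edgeR called no transcript. The spread between the 2 libraries of a group is a candidate explanation. With the estimated dispersions 20% of simulated 4-fold and 54% of 8-fold changes were called. These changes were simulated only in transcripts with a mean of at least 5 CPM. The simulated spread may exceed the real one, so these shares may be too low. The common biological coefficient of variation was 0.729 over all tested transcripts and 0.399 at a mean of at least 5 CPM. It was 0.374 for sums over 5 random rows and 0.312 for sums over 5 consecutive rows. Most of the fall from 0.729 was thus also seen without summing neighbouring rows. Whether the rest reflects a spread at the transcript level was not settled, since the random sums came from a single draw. A library under the wrong group label could also leave no calls. The other splits stand for a swap of 2 libraries, and a single wrong label was not fitted. These splits had 1822 and 1807 transcripts at an unadjusted p below 0.05 against 1399 for KD against VC, but 0 edgeR calls each. DESeq2 called 1370 for VC 1 and KD 2 against VC 2 and KD 1, 369 in the remaining split and 345 for KD against VC. A wrong label and a small effect of the knockdown thus cannot be told apart without the level of PLAG1. A weak knockdown, or one whose effects are small at the time sampled, stays open and untested.

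One well-read transcript is given as an example of wide differences within a group, chosen after its values were seen and not by a ranking. Among transcripts with a mean of at least 5 CPM, 797 had a fitted change of at least 2-fold, none past the test. uc001yhs.4, 1599 nt, had 1493 reads in VC 1 and 11216 in VC 2, and 63 in KD 1 and 594 in KD 2. In CPM these were 84.7 and 549 in VC and 3.82 and 29.7 in KD, so both KD libraries lay below both VC libraries, while the libraries of each group differed widely. The edgeR adjusted p was 1.00.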
